A study of Mus musculus with 12 samples.

How the data were processed

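RNA of mouse astrocyte cultures was sequenced in 12 libraries: cortex and midbrain, each as mock and after 2 or 4 weeks of shPTB in differentiation medium, 2 libraries in each of the 6 groups. Per the labels' protocols, total RNA was primed with a biotinylated oligo(dT)-type primer, captured on streptavidin and given a random-primed second strand, so reads lie towards the 3′ ends of transcripts, and no molecular identifiers are described. Salmon divides reads that match several transcripts among them, and PCR copies were counted as reads. Per the submitters' processing notes, cutadapt 2.3, Salmon 0.14.1, DESeq2 and the mouse build mm10 were used, and the annotation release is not given in the sources used here. The deposited estimated counts were made by the authors with Salmon per transcript and library, without normalization between libraries. The deposited TPM values are scaled within a library by effective length, and served only to weight transcript lengths in an alternative with a length offset.

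Transcripts were assigned to genes with GENCODE M21 on GRCm38. Of 140658 transcripts, 140137 matched and 521, with 0.0547 to 0.129% of reads, were left out. Estimated counts were summed to 54356 genes and rounded to whole numbers, since 56.3% of the values over 0 were not whole. Genes were kept by filterByExpr of edgeR (count minimum 10, total minimum 15), which left 14607. Library sizes were scaled by TMM (factors 1.22 to 1.69 in mock and 0.680 to 0.953 in shPTB libraries). The quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 was fitted to all 6 groups with 1 shared estimate of the spread (common dispersion 0.0550, 6 residual degrees of freedom). It gave 11 contrasts: 2 and 4 weeks against mock and against each other in each region, midbrain against cortex in each state, and the difference of the regions' responses at 2 and at 4 weeks. P-values were adjusted by the Benjamini-Hochberg method within a contrast, with a threshold of 0.05, and every adjusted p of a gene is from edgeR unless another tool is named.

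The 23 gene lists, the contrasts, the tests, the rule for named genes and most alternatives were fixed before the data were examined. They covered astrocyte, neuronal, progenitor and proliferation genes, metabolism, stress and interferon responses, and markers of other cell types, and held 454 genes. Each was tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over 253 tests, with an estimated correlation and fry as alternatives. Lists overlap: 8 of 30 pan-neuronal markers, 5 of 17 fibroblast markers and 4 of 20 matrix genes were also in another list, and all 18 microglia markers and 8 of 17 oligodendrocyte markers had at least 1 CPM in mock. Genes named were a fixed set of 27 target, astrocyte and neuronal genes, the 2 members with the largest change from each other list that passed camera, and the 4 largest rises and falls with a mean of at least 10 CPM in the higher group and no overlap between the groups' libraries. For contrasts other than those with mock, up to 3 called members of each of the neuron-subtype lists were added. Some genes reached by this rule are not reported here. Where a group had 0 reads, a fold was computed against 3 reads over the group, and with 1 to 3 reads the ratio is given with an exact 95% counting interval. The differences of the regions' responses carry no such bound or interval. The share of each gene's 3′ end held by another gene was the share of 31-base words in the last 500 bases of its longest transcript.

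The procedure was tested on counts simulated for cortex at 2 weeks from the libraries' means and sizes, with 200 genes changed. Over 13459 genes, edgeR recovered 0% of genes changed 1.5-fold, 10.4% of those changed 2-fold and 72.7% of those changed 4-fold. Of its calls, 15.2% were unchanged genes, and 23.9% of those over 13433 genes when mock and shPTB libraries kept their own spread. Alternatives were RLE size factors, DESeq2 1.42.0, no count filter, a strict filter (5 CPM in 2 libraries), a transcript length offset, a replicate block, only the groups compared, and each library left out, where a lone library is assumed to vary like the other groups. Added after seeing the data were leaving out both mock libraries of 1 number, a replicate block across regions in mock, leaving out 37 mitochondrial genes or 1275 pseudogenes, limma with library weights, scaling to total reads, and the simulations of unchanged groups, with a correlation of 0.7 between same-numbered mock libraries or none. Splits of the samples were not permuted, since groups held 2 libraries.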

Results

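C57BL/6 mouse astrocytes were grown from cortex or midbrain and sequenced in 3 states: mock cultures in growth medium, and cultures given a short hairpin RNA against PTB (shPTB, directed at Ptbp1) and held in neuronal differentiation medium for 2 or 4 weeks. The 6 groups of 2 libraries made 12 libraries, and the hairpin and the medium changed together, so their effects were not separable. PTB is an RNA-binding protein that represses neuronal splicing, and the series asks how astrocyte and neuronal expression moves when it is depleted. Reads per library ran from 6022098 to 11385761. A count of 0 in a library allowed up to 3 reads, which is 0.163 to 0.576 CPM, and floors and intervals (exact, 95%) cover counting error only. The labels do not say that replicates were separate cultures or animals, so p-values measure only the spread between these libraries. Gene values in parentheses are log2 fold changes ± standard error from edgeR, and levels are CPM (read counts relative to library size, TMM-scaled), mean ± SD, n = 2. List medians at bounds set genes with 0 reads in a group to the bound that 3 reads allow.

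Mitochondrially encoded genes took 18.9 and 22.7% of reads in cortex mock and 16.9 and 18.3% in midbrain mock. They took 37.8 and 38.7% in cortex 2-week and 38.3 and 38.0% in midbrain 2-week libraries, and 47.7 and 48.3% in cortex 4-week and 36.4 and 37.2% in midbrain 4-week libraries. Scaling to total reads instead of TMM moved the median of all genes against mock from -0.11 to -0.85 (cortex 2-week), -0.12 to -1.21 (cortex 4-week), -0.07 to -0.74 (midbrain 2-week) and -0.15 to -1.01 (midbrain 4-week). The mock replicates lay further apart than the shPTB replicates: 10.5% of genes in cortex mock and 8.41% in midbrain mock differed more than 2-fold between replicates, against 0.869 to 2.01% in the other groups.

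Ptbp1 (ENSMUSG00000006498.16, chromosome 10, 79854427 to 79864771, plus strand, GRCm38), the gene the hairpin targets, fell in cortex from 212 ± 55.3 CPM in mock to 73.3 ± 0.357 at 2 weeks (-1.53 ± 0.21, adjusted p = 0.000267) and 89.9 ± 0.931 at 4 weeks (-1.24 ± 0.21, adjusted p = 0.000814). In midbrain it fell from 229 ± 29.8 to 98.0 ± 10.2 CPM at 2 weeks (-1.22 ± 0.21, adjusted p = 0.00122). At 4 weeks in midbrain it stood at 162 ± 9.84 CPM (-0.50 ± 0.20, adjusted p = 0.0744), which did not pass the edgeR test, although all 8 shPTB libraries lay lower than both mock libraries of their region. Its paralogue Ptbp2 (ENSMUSG00000028134.11, chromosome 3, 119718742 to 119784466, minus strand), the neural PTB form, rose in all 4 comparisons, from 8.06 ± 3.34 to 23.9 ± 0.172 and 33.0 ± 1.39 CPM in cortex and from 7.30 ± 1.20 to 26.8 ± 1.18 and 24.6 ± 1.19 CPM in midbrain. Rest, a repressor of neuronal genes in other cell types, fell at 4 weeks in cortex (-1.80 ± 0.52, adjusted p = 0.0171) and midbrain (-1.65 ± 0.49, adjusted p = 0.0205), and at 2 weeks was -1.25 ± 0.48 (adjusted p = 0.0645) and -1.30 ± 0.46 (adjusted p = 0.0530). With an offset for average transcript length the Ptbp1 call ended in cortex at 4 weeks (-0.78, adjusted p = 0.0911) and in midbrain at 2 weeks (-0.98, adjusted p = 0.0525), and that of Ptbp2 ended in cortex at 2 and 4 weeks (0.68 and 0.55) and midbrain at 4 weeks (0.53). Over the 17 alternatives, Ptbp1 in midbrain at 4 weeks ran from -1.36 to -0.08, and 13 of them did not pass. The Rest call was lost in cortex without mock library 1 (adjusted p = 0.112) and 4-week library 2 (adjusted p = 0.139), and in midbrain without mock library 1 (adjusted p = 0.164), 4-week library 1 (adjusted p = 0.0933) and 4-week library 2 (adjusted p = 0.114).

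**Figure D1:**
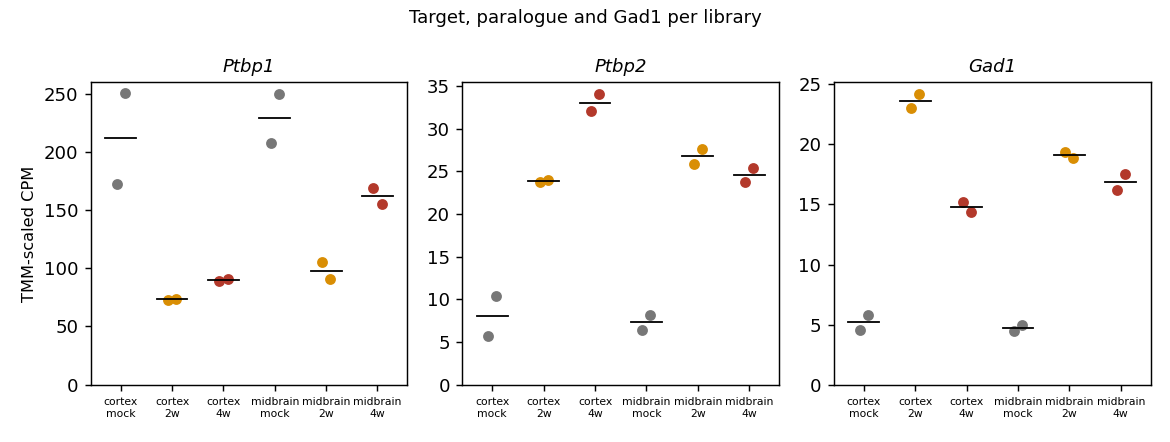
TMM-scaled CPM of Ptbp1, Ptbp2 and Gad1 in each library (points) by group, with the group mean (line). Ptbp1 is lower and Ptbp2 higher in every shPTB library than in both mock libraries of the same region, and Gad1 means rise from 5.2 to 23.6 CPM in cortex at 2 weeks.

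In cortex at 2 weeks of shPTB, 24 of 28 tested proliferation genes (camera adjusted p = 9.59e-14) and 17 of 18 tested microglia markers (adjusted p = 9.54e-22) fell against mock. In the same libraries 9 of 16 tested interferon-response genes (camera adjusted p = 1.55e-05) and 7 of 11 tested oligodendrocyte and precursor markers (adjusted p = 5.99e-06) rose, beside the larger mitochondrial share. The cell-cycle genes Plk1, a mitotic kinase (60.3-fold lower, interval 10.7 to 2395), and Kif11, a spindle motor (25.1-fold lower, interval 8.47 to 123), fell. The calcium-binding protein gene Calb2 rose from 2.63 ± 1.34 to 165 ± 3.05 CPM, and Ret, a receptor of the GDNF family of growth factors, from 0.217 ± 0.143 to 73.9 ± 0.419 CPM.

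Of the 30 tested astrocyte markers, 9 rose and 9 fell (10 and 11 adjusted over the list alone), with median -0.12, mean 0.13, camera direction up, and camera adjusted p = 0.773. The glutamate transporter Slc1a3 (-0.69 ± 0.16) and the folate enzyme Aldh1l1 (-1.47 ± 0.38) fell. Sox9, a glial transcription factor, rose (0.57 ± 0.19) but was -0.14 scaled to total reads. Gfap, the astrocyte intermediate filament, stood at 15257 ± 5869 and 12368 ± 498 CPM (-0.30 ± 0.28, adjusted p = 0.434, and 0.15 without both mock libraries numbered 2). The water channel Aqp4 (-0.29 ± 0.20) and the connexin Gja1 (-0.28 ± 0.25) did not pass the test either. Among pan-neuronal markers, 12 of 26 tested rose and 5 fell (12 and 6 alone), with median 0.82 and camera adjusted p = 0.182. Rbfox3, the NeuN antigen (2.72 ± 0.59), Snap25, a synaptic fusion protein (3.01 ± 0.66), and the vesicle protein gene Syn1 (1.12 ± 0.21) rose, the first 2 from under 1 CPM (0.304 and 0.315) to 2.06 and 2.55 CPM. Tubb3, a neuronal tubulin (-1.53 ± 0.28), and Dcx, a protein of migrating neurons (-1.34 ± 0.25), fell, and Map2 was -0.26 ± 0.21 (adjusted p = 0.345). Leaving out 1 cortex library at a time ended the edgeR call of Aldh1l1, Sox9 and Th (adjusted p = 0.0703 to 0.196) without mock library 1 and 2-week 1 or 2, and for Nr4a2 (adjusted p = 0.0896 to 0.243) without each of the 4 libraries. It was also lost for Slc1a3 (adjusted p = 0.0662 and 0.0624) without 2-week library 1 or 2, and for Col3a1 (adjusted p = 0.0506) without 2-week library 1. The call further ended for Rbfox3 and Snap25 (adjusted p = 0.0530 and 0.0770) without 2-week library 2. Calls also ended scaled to total reads for Syn1, Th and Nr4a2 (0.41, 2.16 and 0.83, adjusted p = 0.105, 0.0599 and 0.248). With the length offset, library weights, DESeq2, no count filter, only the groups compared or both mock libraries numbered 1 or 2 left out, calls of Nr4a2, Sox9, Th, Slc1a3, Rbfox3 and Snap25 ended (adjusted p = 0.0501 to 0.429).

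**Figure D2:**
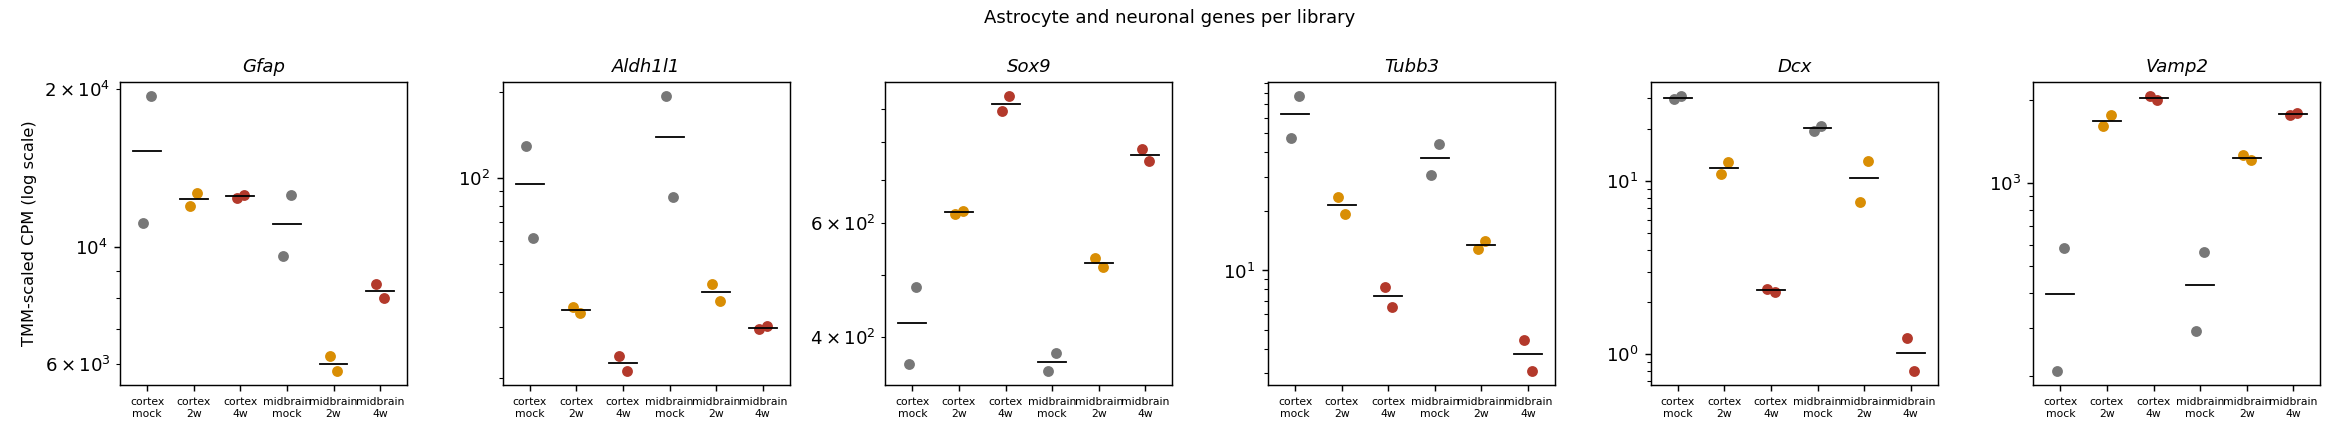
TMM-scaled CPM, on a log axis, of Gfap, Aldh1l1, Sox9, Tubb3, Dcx and Vamp2 in each library (points) by group, with the group mean (line). Dcx means fall from 30.3 to 2.34 CPM in cortex and from 20.1 to 1.02 CPM in midbrain at 4 weeks.

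Among synaptic vesicle and release genes, 12 of 22 tested rose (12 higher and 1 lower adjusted over the list alone), with median 1.10 and camera adjusted p = 0.000243, adjusted p = 0.0963 with an estimated correlation. Its largest rises were Syt4, a synaptotagmin (5.05 ± 0.34), and Dnm1, the dynamin of vesicle recycling (3.75 ± 0.40). Among GABAergic neuron genes, 4 of 12 tested rose and 3 fell (4 and 3 alone), with median 0.59, but -0.16 scaled to total reads, and camera adjusted p = 0.00515, adjusted p = 0.122 with an estimated correlation. Calb2 (5.99 ± 0.31), the neuropeptide gene Sst (5.04 ± 0.50) and the GABA-synthesis enzyme Gad1 (2.19 ± 0.19) rose, and Gad2 was 0.30 ± 0.43 (adjusted p = 0.615). Among dopaminergic and midbrain genes, 6 of 12 tested rose (7 higher alone), with median 1.52 and camera adjusted p = 0.000225, adjusted p = 0.122 with an estimated correlation. Ret (8.42 ± 0.40), the midbrain factor En1 (3.32 ± 0.46), Th, the rate-limiting enzyme of dopamine synthesis (2.82 ± 0.89), and Nr4a2 (1.55 ± 0.55) rose, with Th at 0.228 and 1.56 CPM. Among glutamatergic and cortical neuron genes, 1 of 10 tested rose and 3 fell (2 and 3 alone), with median -0.25 and camera adjusted p = 0.556. The vesicular glutamate transporter gene Slc17a6 and the dopamine transporter gene Slc6a3 had 0 reads in all 12 libraries, Slc17a7 had 0 to 7, Lmx1a 0 to 3 and Foxa2 1 read in 1 library, so these 5 genes were not detectable or not testable at this depth. Among neurogenic transcription factors, 6 of 11 tested fell (6 lower alone), with median -1.18 and camera adjusted p = 0.0144, adjusted p = 0.0980 with an estimated correlation. Insm1 (-3.77 ± 0.56) and Sox11 (-2.54 ± 0.27), factors of developing neurons, fell most.

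The proliferation genes had median -3.11, with 25 lower adjusted over the list alone. The microglia markers had median -3.71, with 17 lower over the list alone. Cx3cr1, the fractalkine receptor (210.1-fold lower, interval 71.8 to 1020.0), and the actin-binding protein gene Aif1 (65.5-fold lower, interval 18 to 543) fell. Among extracellular matrix genes, 1 of 19 tested rose and 13 fell (1 and 13 alone), with median -1.79 and camera adjusted p = 1.15e-05, adjusted p = 0.0549 with an estimated correlation. The collagens Col5a2 (-4.21 ± 0.74) and Col3a1 (13.9-fold lower, interval 3.71 to 117) fell. Among fibroblast and pericyte markers, 5 of 16 tested rose and 9 fell (5 and 10 alone), with median -2.16 and camera adjusted p = 0.000153, adjusted p = 0.0747 with an estimated correlation. The contractile genes Tagln (-6.37 ± 0.48) and Acta2 (-5.57 ± 0.25) fell, the latter from 296 ± 47.6 to 6.22 ± 0.996 CPM. Among ependymal and choroid plexus markers, 1 of 14 tested rose and 10 fell (2 and 10 alone), with median -1.90 and camera adjusted p = 0.00157, adjusted p = 0.0507 with an estimated correlation. The cilium genes Pifo (157-fold lower, interval 28.1 to 6225) and Dnah9 (58.1-fold lower, interval 16.0 to 482) fell. The interferon-response genes had median 1.78, with 11 higher and 2 lower over the list alone (9 rose and 1 fell over all genes). Ifit1 (4.22 ± 0.21) and Usp18 (3.62 ± 0.39) rose most. The oligodendrocyte and precursor markers had median 1.10, with 7 higher and 2 lower over the list alone (7 rose and 2 fell over all genes). The myelin genes Mag (5.76 ± 0.51) and Mbp (4.74 ± 0.23) rose.

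Camera did not pass in cortex at 2 weeks for genes of the PTB and REST axis (3 of 16 rose and 3 fell, 3 and 5 adjusted over the list alone, median -0.18, adjusted p = 0.862), neural progenitor genes (1 of 15 rose and 7 fell, 1 and 7 alone, median -0.38, adjusted p = 0.0581) and cholesterol biosynthesis genes (4 of 22 rose and 3 fell, 4 and 2 alone, median -0.03, mean -0.07, camera direction up, adjusted p = 0.912). Nor did it for reactive astrocyte genes (8 of 27 rose and 9 fell, 9 and 9 alone, median -0.26, mean 0.28, camera direction up, adjusted p = 0.382) and endothelial markers (0 of 8, 0 alone, median -0.12, mean 0.02, camera direction down, adjusted p = 0.963). The 4 lists not named for this comparison did not pass (adjusted p = 0.469 to 0.887).

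The largest rises were the protease gene Klk6 (891-fold higher, interval 159 to 35276), Ret, the transcription factor Mafa (8.21 ± 0.40) and the secreted hormone gene Stc1 (7.32 ± 0.24). The largest falls were Plp2 (at least 72.4-fold lower), Cx3cr1, the leukotriene synthase gene Ltc4s (188-fold lower, interval 52.0 to 1557) and Fcrls, an Fc receptor-like gene of microglia (-7.42 ± 0.36). Plp2 shares 93.4% of its 3′ end with another gene, so its count is uncertain. In edgeR, 5117 of 14607 genes passed, 2549 higher and 2568 lower, 1928 and 2135 of them by at least 2-fold. The share of calls that was higher, 49.8%, was 16.5% scaled to total reads. The count was 3129 and 2966 without cortex 2-week library 1 or 2, and 8385 without both mock libraries numbered 2.

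In cortex at 4 weeks, 25 of 28 tested proliferation genes (camera adjusted p = 1.59e-14), 17 of 18 tested microglia markers (adjusted p = 1.61e-26) and 15 of 19 tested extracellular matrix genes (adjusted p = 1.64e-11) fell against mock. Dcx fell from 30.3 ± 0.973 to 2.34 ± 0.0530 CPM and Tubb3 from 62.4 ± 21.1 to 7.39 ± 1.21 CPM. Aldh1a1, a retinaldehyde dehydrogenase, rose from 45.2 ± 11.1 to 1119 ± 44.7 CPM. Of the fixed astrocyte genes, Slc1a3 (-1.32 ± 0.17), Aldh1l1 (-2.09 ± 0.40), Aqp4 (-0.95 ± 0.20) and Gja1 (-0.95 ± 0.26) fell and Sox9 rose (1.13 ± 0.19). Gfap was -0.29 ± 0.28 (adjusted p = 0.454), and 0.17 without both mock libraries numbered 2. Among astrocyte markers, 8 of 30 tested rose and 10 fell (9 and 10 adjusted over the list alone), with median -0.02, mean 0.06, camera direction up, and camera adjusted p = 0.850.

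Of the 26 tested pan-neuronal markers, 7 rose and 6 fell (7 and 6 adjusted over the list alone), with median 0.16, but -0.89 scaled to total reads, mean -0.13, camera direction down, and camera adjusted p = 0.843. Syn1 rose (1.31 ± 0.21), Tubb3 (-3.07 ± 0.31) and Dcx (-3.68 ± 0.31) fell, and Map2 (-0.33 ± 0.21), Rbfox3 (0.30 ± 0.77) and Snap25 (1.07 ± 0.78) did not pass. Among synaptic vesicle and release genes, 9 of 22 tested rose and 1 fell (10 and 2 alone), with median 0.73, but -0.37 scaled to total reads, and camera adjusted p = 0.00478, adjusted p = 0.148 with an estimated correlation. Syt4 (4.57 ± 0.34) and Dnm1 (3.29 ± 0.40) rose most. Among dopaminergic and midbrain genes, 4 of 12 tested rose (4 higher alone), with median 0.92, but -0.13 scaled to total reads, and camera adjusted p = 0.00218, adjusted p = 0.149 with an estimated correlation. Ret (6.93 ± 0.40), Aldh1a1 (4.63 ± 0.28) and En1 (3.04 ± 0.47) rose, Th was 2.21 ± 0.94 (adjusted p = 0.0836), and Nr4a2 was at 0.284 CPM (1.67-fold lower, interval 0.466 to 9.07). Gad1 rose (1.51 ± 0.20), while Gad2 (-0.76 ± 0.48) did not pass. Camera did not pass for GABAergic neuron genes (5 of 12 rose and 3 fell, 5 and 3 alone, median 0.22, but -0.88 scaled to total reads, mean -0.12, camera direction up, adjusted p = 0.220) and interferon-response genes (2 of 16 rose and 4 fell, 2 and 4 alone, median -0.60, adjusted p = 0.723). The 9 lists not named for this comparison did not pass (adjusted p = 0.104 to 1.0). Among cholesterol biosynthesis genes, 9 of 22 tested rose and 1 fell (9 and 1 alone), with median 0.37, but -0.69 scaled to total reads, and camera adjusted p = 0.0313, adjusted p = 0.118 with an estimated correlation. The sterol regulator Insig1 (2.36 ± 0.27) and the sterol oxidase Msmo1 (1.67 ± 0.18) rose most. Omitting 1 library at a time ended the edgeR call for Gja1 (adjusted p = 0.0987 and 0.111) without mock library 1 and 4-week 2. They also ended scaled to total reads for Sox9, Syn1 and Gad1 (0.07, 0.26 and 0.45, adjusted p = 0.642, 0.269 and 0.0647). With the length offset or only the groups compared, calls of Sox9 and Gja1 ended (adjusted p = 0.050002 to 0.0750).

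The proliferation genes had median -4.51, or -3.90 at bounds, with 27 lower adjusted over the list alone. Rrm2, a subunit of ribonucleotide reductase (at least 27-fold lower), and Kif11 (at least 23.3-fold lower) fell to 0 reads. Among reactive astrocyte genes, 5 of 27 tested rose and 13 fell (5 and 13 alone), with median -1.12 and camera adjusted p = 0.00864, adjusted p = 0.111 with an estimated correlation. Emp1 (at least 14.8-fold lower) and the transglutaminase Tgm1 (at least 8.24-fold lower) fell most. The extracellular matrix genes had median -2.73, with 1 higher and 16 lower over the list alone. Col3a1 (at least 8.59-fold lower) and Lox, which cross-links collagen (39.7-fold lower, interval 10.9 to 330.2), fell. The microglia markers had median -5.77, with 1 higher and 17 lower over the list alone. Cx3cr1 (-7.16 ± 0.61) and the complement gene C1qa (-6.81 ± 0.42) fell, C1qa from 128 ± 22.3 to 1.14 ± 0.834 CPM. Among fibroblast and pericyte markers, 3 of 16 tested rose and 9 fell (3 and 10 alone), with median -2.97, or -2.68 at bounds, and camera adjusted p = 1.39e-07. Anpep was at least 6.21-fold lower. Among ependymal and choroid plexus markers, 1 of 14 tested rose and 9 fell (1 and 10 alone), with median -2.28 and camera adjusted p = 0.00158, adjusted p = 0.0507 with an estimated correlation. Dnah5 (at least 11.6-fold lower) and the water channel Aqp1 (105-fold lower, interval 28.8 to 865) fell. Among oligodendrocyte and precursor markers, 6 of 11 tested rose and 3 fell (6 and 3 alone), with median 1.03, but -0.04 scaled to total reads, and camera adjusted p = 0.00131, adjusted p = 0.0587 with an estimated correlation. Mag (5.34 ± 0.51) and Mbp (4.67 ± 0.23) rose.

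The largest rises at 4 weeks in cortex were Klk6 (1025-fold higher, interval 183 to 40591), Mafa (8.05 ± 0.40), the secretogranin Scg2 (346-fold higher, interval 61.0 to 13787) and Prima1, an acetylcholinesterase anchor (7.72 ± 0.40). The largest falls were the purinergic receptor P2ry13 (at least 50.4-fold lower), the apolipoprotein Apoc2 (at least 49.1-fold lower), Cbr2 (406-fold lower, interval 72.7 to 16038) and the matrix protein gene Mgp (369.5-fold lower, interval 66.2 to 14609.8). Apoc2 and Cbr2 share 98.9 and 42.1% of the 3′ end with other genes, so these are uncertain. In edgeR, 5753 genes passed, 2705 higher and 3048 lower, 1961 and 2670 by at least 2-fold. The higher share was 47.0%, and 9.28% of 9201 calls scaled to total reads. The count was 3686 and 3755 without cortex 4-week library 1 or 2.

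Between 2 and 4 weeks in cortex, 8 of 16 tested interferon-response genes (camera adjusted p = 2.15e-25), 9 of 27 tested reactive astrocyte genes (adjusted p = 2.15e-25) and 7 of 19 tested extracellular matrix genes (adjusted p = 3.15e-12) fell. The aldehyde dehydrogenase Aldh1a7 rose from 55.2 ± 6.67 to 976 ± 15.5 CPM and the related Aldh1a1 from 329 ± 4.24 to 1119 ± 44.7 CPM (1.77 ± 0.25). Calb2 fell from 165 ± 3.05 to 21.2 ± 0.455 CPM (-2.96 ± 0.26), Ret also fell (-1.49 ± 0.26), and Fezf2, a factor of deep-layer cortical neurons, rose (1.73 ± 0.35).

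The interferon-response genes had median -1.72, or -1.64 at bounds, with 13 lower adjusted over the list alone. The reactive astrocyte genes had median -1.24, or -1.12 at bounds, with 1 higher and 19 lower over the list alone. The extracellular matrix genes had median -1.14, or -1.02 at bounds, with 10 lower over the list alone. Camera also passed, but not with an estimated correlation (adjusted p = 0.0638 to 0.122), for pan-neuronal markers (4 of 26 fell, 11 over the list alone, median -0.55, adjusted p = 3.36e-05) and GABAergic neuron genes (0 of 12 rose and 1 fell, 1 and 3 alone, median -0.67, or -0.66 at bounds, adjusted p = 0.000690). This held too for proliferation genes (2 of 28 fell, 3 alone, median -1.26, or -0.82 at bounds, adjusted p = 0.00763). With both correlations it passed for cholesterol biosynthesis genes (3 of 22 rose, 7 alone, median 0.56, adjusted p = 6.36e-07) and microglia markers (6 of 18 fell, 9 alone, median -1.52, adjusted p = 2.30e-10). It did so too for fibroblast and pericyte markers (4 of 16 fell, 5 alone, median -1.06, or -0.52 at bounds, adjusted p = 5.99e-06).

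Beside Aldh1a7 (4.15 ± 0.40) and Aldh1a1, the largest rises were the collagen Col22a1 (2.43 ± 0.25) and the phosphatase inhibitor Ppp1r1b (2.19 ± 0.26). The largest falls were the interferon-inducible GTPase Tgtp2 (at least 36.8-fold lower, 100% of its 3′ end shared), the antibacterial lectin Reg3g (-5.67 ± 0.48), the peptide transporter Slc15a3 (-4.05 ± 0.35) and Lrg1 (-4.00 ± 0.50). In edgeR 405 genes passed, 80 higher and 325 lower, a higher share of 19.8%, against 4.07% of 933 calls when scaled to total reads, which moved the median of all genes to -0.35. Leaving out cortex 2-week library 1 or 2 gave 85 and 99 calls, and cortex 4-week library 1 or 2 gave 43 and 52. Single calls also ended for Aldh1a1, Ret and Fezf2 (adjusted p = 0.0518 to 0.240) without each of the 4 libraries, and for Lrg1 (adjusted p = 0.0623) without 4-week library 1. With total-reads scaling or the length offset, calls of Ret, Col22a1 and Fezf2 ended (adjusted p = 0.0506 to 0.189). There were 2608 genes when only these groups were fitted and 1832 in limma with library weights.

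In midbrain at 2 weeks, 22 of 28 tested proliferation genes (camera adjusted p = 7.99e-14), 17 of 18 tested microglia markers (adjusted p = 1.08e-27) and 15 of 19 tested extracellular matrix genes (adjusted p = 4.85e-10) fell against mock, and 7 of 16 tested interferon-response genes (camera adjusted p = 0.000290) rose. Sst rose from 0.232 ± 0.0556 to 73.4 ± 6.60 CPM and Reg3g from 0.607 ± 0.322 to 332 ± 18 CPM. Acta2 fell from 766 ± 136 to 9.61 ± 0.145 CPM. Gfap fell from 11095 ± 2099 to 6012 ± 269.8 CPM (-0.88 ± 0.29) and Aldh1l1 fell (-1.80 ± 0.38).

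Of the 30 tested astrocyte markers, 7 rose and 7 fell (9 and 7 adjusted over the list alone), with median 0.26, but -0.40 scaled to total reads, and camera adjusted p = 0.729. Slc1a3 (-0.27 ± 0.16), Gja1 (-0.17 ± 0.25), Sox9 (0.51 ± 0.19) and Aqp4 (0.15 ± 0.20) did not pass, and Aqp4 was -0.50 scaled to total reads. Among pan-neuronal markers, 6 of 26 tested rose and 6 fell (7 and 6 alone), with median 0.00, but -0.66 scaled to total reads, mean 0.09, camera direction down, and camera adjusted p = 1.0. Tubb3 (-1.46 ± 0.28) and Dcx (-0.96 ± 0.25) fell, Syn1 rose (0.83 ± 0.22), and Map2 (-0.06 ± 0.20), Rbfox3 (0.05 ± 0.53) and Snap25 (1.13 ± 0.66) did not pass. Among synaptic vesicle and release genes, 7 of 22 tested rose and 2 fell (7 and 3 alone), with median 0.34, but -0.30 scaled to total reads, and camera adjusted p = 0.239. Among GABAergic neuron genes, 4 of 12 tested rose and 2 fell (4 and 2 alone), with median -0.07, mean 0.75, camera direction up, and camera adjusted p = 0.0169, adjusted p = 0.160 with an estimated correlation. Sst (8.21 ± 0.49), Calb2 (5.62 ± 0.30) and Gad1 (2.02 ± 0.19) rose, and Gad2 was 0.15 ± 0.43. Among dopaminergic and midbrain genes, 6 of 12 tested rose and 2 fell (7 and 2 alone), with median 0.98 and camera adjusted p = 0.00474, adjusted p = 0.181 with an estimated correlation. Ret (283-fold higher, interval 77.7 to 2349) and En1 (3.02 ± 0.40) rose, Nr4a2 was 1.21 ± 0.50 (adjusted p = 0.0865), and Th had 2 reads over the group at 2 weeks against 9 in mock (2.37-fold lower, interval 0.490 to 22.5). Without 1 midbrain library the edgeR call ended for Syn1 (adjusted p = 0.0552 to 0.0759) without mock library 1 and 2-week 1 or 2, and for Gfap (adjusted p = 0.113 to 0.182) without mock library 2 and 2-week 1 or 2. Losses also followed for Dcx (adjusted p = 0.133) without 2-week library 1, and for Aldh1l1 (adjusted p = 0.0516) without 2-week library 2. It also ended scaled to total reads for Syn1 (0.16, adjusted p = 0.523). With the length offset or only the groups compared, calls of Gfap, Dcx and Syn1 ended (adjusted p = 0.0565 to 0.0995).

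Among neurogenic transcription factors, 1 of 11 tested rose and 6 fell (1 and 8 adjusted over the list alone), with median -1.47 and camera adjusted p = 0.00318, adjusted p = 0.0604 with an estimated correlation. Insm1 (-3.13 ± 0.49) and Sox11 (-3.04 ± 0.27) fell most. The proliferation genes had median -2.45, or -2.39 at bounds, with 23 lower over the list alone. Mcm6, a replication helicase subunit (-4.68 ± 0.53), and the checkpoint kinase Bub1 (15.6-fold lower, interval 5.17 to 77.1) fell. The microglia markers had median -4.09, with 1 higher and 17 lower over the list alone (1 rose and 17 fell over all genes). C1qc (-6.91 ± 0.35) and Cx3cr1 (-6.47 ± 0.54) fell. The tested extracellular matrix genes had median -1.55, with 2 higher and 16 lower over the list alone (2 rose and 15 fell over all genes). Periostin, Postn (-3.87 ± 0.39), and Col6a2 (-3.35 ± 0.23) fell. Among fibroblast and pericyte markers, 5 of 16 tested rose and 8 fell (5 and 9 alone), with median -1.59 and camera adjusted p = 0.000112, adjusted p = 0.0659 with an estimated correlation. Acta2 (-6.32 ± 0.25) and Tagln (-5.78 ± 0.40) fell. The interferon-response genes had median 1.35, with 9 higher over the list alone. Ifit1 (3.41 ± 0.20) and Usp18 (3.11 ± 0.37) rose. Camera did not pass for oligodendrocyte and precursor markers (6 of 11 rose and 2 fell, 6 and 2 alone, median 1.05, adjusted p = 0.278). The 11 lists not named for this comparison did not pass (adjusted p = 0.0517 to 1.0).

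The largest rises were the epithelial envelope gene Sprr2b (at least 149-fold higher, 25.3% of its 3′ end shared), Reg3g (9.10 ± 0.44), the amino acid transporter Slc6a20a (430.1-fold higher, interval 147 to 2091) and Sst, and the largest falls were Fcrls (-6.91 ± 0.33), C1qc, Cx3cr1 and the microfibril gene Mfap4 (-6.35 ± 0.31). In edgeR 4470 genes passed, 2317 higher and 2153 lower, 1749 and 1732 by at least 2-fold. The higher share was 51.8%, and 17.1% of 6833 calls scaled to total reads. The count was 2424 and 2478 without midbrain 2-week library 1 or 2, and 8413 without both mock libraries numbered 2.

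In midbrain at 4 weeks, 26 of 28 tested proliferation genes (camera adjusted p = 4.28e-16), 17 of 18 tested microglia markers (adjusted p = 1.74e-28) and 16 of 19 tested extracellular matrix genes (adjusted p = 8.19e-12) fell against mock, and 10 of 16 tested interferon-response genes (camera adjusted p = 2.86e-06) rose. The neural stem cell filament Nes fell from 91.3 ± 14.0 to 7.80 ± 1.46 CPM and Dcx from 20.1 ± 1.10 to 1.02 ± 0.311 CPM. Aldh1a1 rose from 39.8 ± 13.4 to 872 ± 19.6 CPM, and Ifit1 from 3.35 ± 0.475 to 84.8 ± 2.26 CPM. Slc1a3 (-1.22 ± 0.17), Aldh1l1 (-2.22 ± 0.39), Aqp4 (-0.63 ± 0.20) and Gja1 (-0.97 ± 0.25) fell, Sox9 rose (1.06 ± 0.19) and Gfap was -0.43 ± 0.28 (adjusted p = 0.258). Among astrocyte markers, 10 of 30 tested rose and 9 fell (12 and 9 adjusted over the list alone), with median 0.07, but -0.79 scaled to total reads, and camera adjusted p = 0.751.

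Of the 26 tested pan-neuronal markers, 5 rose and 10 fell (5 and 11 adjusted over the list alone), with median -0.60 and camera adjusted p = 0.159. Tubb3 (-3.31 ± 0.32), Dcx (-4.29 ± 0.33) and Rbfox3 (4.76-fold lower, interval 1.49 to 24.2) fell, Syn1 rose (1.14 ± 0.22), and Map2 (-0.48 ± 0.20) and Snap25 (0.34 ± 0.74) did not pass. Among synaptic vesicle and release genes, 10 of 22 tested rose and 7 fell (10 and 7 alone), with median 0.40, but -0.47 scaled to total reads, and camera adjusted p = 0.255. Gad1 rose (1.84 ± 0.19) and Gad2 (-1.97 ± 0.55) fell. Among dopaminergic and midbrain genes, 6 of 12 tested rose and 2 fell (6 and 3 alone), with median 0.66, but -0.20 scaled to total reads, and camera adjusted p = 0.00736, adjusted p = 0.194 with an estimated correlation. Ret (257-fold higher, interval 70.2 to 2133), Aldh1a1 (4.45 ± 0.28) and En1 (2.72 ± 0.41) rose, and Th (0.03 ± 1.03) and Nr4a2 (0.34 ± 0.54) did not pass. Camera missed the threshold for GABAergic neuron genes (4 of 12 rose and 5 fell, 4 and 7 alone, median -1.15, mean -0.08, camera direction up, adjusted p = 0.131) and oligodendrocyte and precursor markers (3 of 11 rose and 2 fell, 4 and 2 alone, median 0.15, but -0.71 scaled to total reads, adjusted p = 0.730). The 10 lists not named for this comparison did not pass (adjusted p = 0.124 to 1.0). When 1 midbrain library was omitted, the edgeR call ended for Gja1 and St18 (adjusted p = 0.0541 to 0.160) without mock library 1 and 4-week 1 or 2, and for Rbfox3 (adjusted p = 0.0729 to 0.178) without each of the 4 libraries. A call ended too for Aqp4 (adjusted p = 0.109 to 0.161) without mock library 2 and 4-week 1 or 2, and for Gad2 (adjusted p = 0.050016 and 0.118) without 4-week library 1 or 2. It was also lost for Oas1a (adjusted p = 0.0682) without 4-week library 1. It ended too scaled to total reads for Sox9 and Syn1 (0.19 and 0.27, adjusted p = 0.183 and 0.256). With library weights, DESeq2, no count filter, only the groups compared or both mock libraries numbered 1 or 2 left out, calls of Rbfox3, Aqp4 and Rest ended (adjusted p = 0.0539 to 0.101).

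Among neurogenic transcription factors, 9 of 11 tested fell (9 lower and 1 higher adjusted over the list alone), with median -1.46 and camera adjusted p = 0.00254, adjusted p = 0.0583 with an estimated correlation. Sox11 (-3.67 ± 0.29) and St18 (9.37-fold lower, interval 3.07 to 46.6) fell most. Among neural progenitor genes, 1 of 15 tested rose and 8 fell (1 and 8 alone), with median -0.93 and camera adjusted p = 0.00818, adjusted p = 0.0747 with an estimated correlation. Nes (-3.55 ± 0.23) and the matrix glycoprotein Tnc (-3.52 ± 0.43) fell. The proliferation genes had median -3.43, or -3.32 at bounds, with 27 lower over the list alone. Kif11 (at least 27-fold lower) and Bub1b (at least 14.4-fold lower) fell. The microglia markers had median -6.22, or -6.03 at bounds, with 1 higher and 17 lower over the list alone. The lysosomal protease Ctss (at least 134-fold lower) and C1qc (-7.83 ± 0.39) fell. The extracellular matrix genes had median -2.30, with 2 higher and 16 lower over the list alone (2 rose and 16 fell over all genes). Postn (-4.74 ± 0.43) and Col5a2 (-4.48 ± 0.61) fell. Among fibroblast and pericyte markers, 5 of 16 tested rose and 9 fell (5 and 10 alone), with median -2.19 and camera adjusted p = 4.51e-05, adjusted p = 0.0638 with an estimated correlation. The proteoglycan Cspg4 (119-fold lower, interval 21.2 to 4713) and Tagln (-6.59 ± 0.44) fell. The interferon-response genes had median 1.81, with 11 higher and 1 lower over the list alone (10 rose and 1 fell over all genes). Ifit1 (4.65 ± 0.21) and Oas1a (3.55 ± 0.89) rose, although 70.0% of the 3′ end of Oas1a is shared with other genes.

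The largest rises were Sprr2b (at least 235-fold higher), Sst (8.29 ± 0.49), Slc6a20a (342-fold higher, interval 116 to 1662) and Ret, and among the largest falls were Ctss, the lysosomal nuclease gene Pld4 (at least 76.0-fold lower) and Fcrls (984-fold lower, interval 272 to 8130.5). In edgeR 5721 genes passed, 2736 higher and 2985 lower, 1998 and 2508 by at least 2-fold. The higher share was 47.8%, and 13.1% scaled to total reads. The count was 3305 and 3399 without midbrain 4-week library 1 or 2, and 8884 without both mock libraries numbered 2.

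Between 2 and 4 weeks in midbrain, 2 of 28 tested proliferation genes (camera adjusted p = 7.66e-05) fell. The prostaglandin synthase gene Ptgds rose from 526 ± 23.4 to 2817 ± 94.2 CPM (2.42 ± 0.19), and the calcium-binding protein Pvalb (1.04 ± 0.17) and Aldh1a1 (1.47 ± 0.25) rose. Dcx fell from 10.4 ± 3.92 to 1.02 ± 0.311 CPM (-3.33 ± 0.34).

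The proliferation genes had median -1.07, or -1.04 at bounds, with 8 lower adjusted over the list alone. Camera also passed, but not with an estimated correlation (adjusted p = 0.0556 to 0.153), for pan-neuronal markers (1 of 26 rose and 5 fell, 2 and 9 over the list alone, median -0.47, adjusted p = 0.000602) and microglia markers (4 of 18 fell, 7 alone, median -1.15, or -1.13 at bounds, adjusted p = 1.64e-06). The same was seen for interferon-response genes (2 of 16 rose, 3 alone, median 0.30, adjusted p = 0.00323) and genes of voltage-gated channels and neurotransmitter receptors (2 of 23 fell, 2 alone, median -0.66, adjusted p = 0.00435). So it was for extracellular matrix genes (1 of 19 fell, 1 alone, median -0.54, adjusted p = 0.00323). The other large rises were Gmip (3.18 ± 0.47), Glycam1 (2.02 ± 0.33) and Resp18 (2.02 ± 0.41), and the other large falls the olfactory receptor gene Olfr1284 (-5.15 ± 0.65, 34.3% of its 3′ end shared), the chemokine Ccl3 (-4.04 ± 0.42) and the lectin Clec4a1 (-3.06 ± 0.37). In edgeR 388 genes passed, 140 higher and 248 lower, a higher share of 36.1%, against 18.2% when scaled to total reads, where the median of all genes was -0.24. Leaving out midbrain 2-week library 1 or 2 gave 38 and 52 calls, and 4-week library 1 or 2 gave 25 in each case. Single calls then ended for Aldh1a1, Pvalb, Gmip, Glycam1 and Resp18 (adjusted p = 0.0584 to 0.286) without each of the 4 libraries, and for Clec4a1 (adjusted p = 0.0788 and 0.0584) without 4-week library 1 or 2. With total-reads scaling or the length offset, calls of Resp18 and Ccl3 ended (adjusted p = 0.0636 to 0.243). The count was 3903 genes when only these groups were fitted and 3057 in limma with library weights.

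The calls of cortex and midbrain against mock overlapped. At 2 weeks 1765 genes were higher in both regions (independent lists would share 404) and 1611 lower (379). At 4 weeks 1990 were higher in both (507) and 2079 lower (623). Genes higher in cortex and lower in midbrain numbered 5 at 2 weeks and 15 at 4 weeks, and the reverse 8 and 46. Across genes, which are not independent replicates, the log2 fold changes of the regions correlated with Pearson's r of 0.796 at 2 weeks and 0.751 at 4 weeks, with covariances of 2.18 and 2.58. Same-numbered mock libraries of the regions deviated together. In 20 simulations of this without change, r was 0.465 to 0.509 and 0.458 to 0.499, and covariances 0.106 to 0.125 and 0.109 to 0.122. At most 2 genes were called higher and 1 lower in both, which without changed genes cannot judge the overlap.

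In mock cultures, 10 of 19 tested extracellular matrix genes (camera adjusted p = 7.97e-42) and 4 of 16 tested fibroblast and pericyte markers (adjusted p = 9.44e-10) were higher in midbrain than in cortex. Otx2, a midbrain and forebrain patterning factor, was higher in midbrain (3.32 against 15 CPM, 2.16 ± 0.23), as was Pvalb (0.85 ± 0.18). The cortical genes Lhx2 (-0.91 ± 0.20) and Camk2a (-0.98 ± 0.19) and the factor Sox6 (-0.96 ± 0.17) were lower. Most different were Wnt8b (5.48 ± 0.52), Postn (5.17 ± 0.42), the elastic fibre gene Fbln5 (4.70 ± 0.20) and Nkd2 (4.64 ± 0.39) on the midbrain side. On the cortex side they were the factor Dmrta2 (-4.96 ± 0.58), Spon2 (-3.24 ± 0.21), the retinol-binding receptor gene Stra6 (-3.18 ± 0.36) and Glycam1 (-2.76 ± 0.31).

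The tested extracellular matrix genes had median 1.37, with 14 higher adjusted over the list alone. The fibroblast and pericyte markers had median 0.77, with 5 higher over the list alone. Camera also passed, but not with an estimated correlation (adjusted p = 0.105 to 0.160), for dopaminergic and midbrain genes (2 of 12 higher and 1 lower, 4 and 1 over the list alone, median 0.87, adjusted p = 0.000690) and astrocyte markers (0 of 30 higher and 2 lower, 1 and 2 alone, median -0.22, adjusted p = 0.0303). Likewise it passed for stress and p53 response genes (3 of 19 higher, 4 alone, median 0.11, adjusted p = 0.0418) and immediate early genes (0 of 9 higher, 2 alone, median 0.55, adjusted p = 0.0290). In edgeR 320 genes passed, 183 higher in midbrain and 137 lower. With the 4 mock libraries fitted alone and unblocked, edgeR called 0 genes (648 at an unadjusted p under 0.05) and DESeq2 121 (505). With a replicate block across regions, added after seeing the data, edgeR called 2200 in these libraries, 316 of them among the 320. In 20 simulations with the wider mock spread and no regional difference, edgeR on all 12 libraries called 152 to 308 genes where mock libraries varied independently, and 0 to 2 where same-numbered ones deviated together. Leaving out both mock libraries numbered 1 or 2 compared 1 library with 1, so the calls there measured no spread between mock libraries. Leaving out 1 mock library ended the call for Lhx2 (adjusted p = 0.0734 to 0.181) without cortex library 1 or 2 and midbrain 1, and for Pvalb (adjusted p = 0.0513 to 0.104) without cortex library 1 and midbrain 1 or 2. The call further ended for Camk2a (adjusted p = 0.0886 and 0.131) without cortex library 2 and midbrain 1, and for Sox6 (adjusted p = 0.0722) without midbrain library 1. With total-reads scaling, the length offset or library weights, calls of Camk2a, Lhx2, Pvalb, Glycam1, Sox6 and Wnt8b ended (adjusted p = 0.0627 to 0.401).

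At 2 weeks of shPTB, 7 of 14 tested ependymal and choroid plexus markers (camera adjusted p = 2.88e-19) and 8 of 19 tested extracellular matrix genes (adjusted p = 1.86e-19) were higher in midbrain than in cortex, and 7 of 11 tested oligodendrocyte and precursor markers (camera adjusted p = 1.86e-19) were lower. Mbp (-3.19 ± 0.22), Mag (-3.45 ± 0.44) and the oligodendrocyte factor Sox10 (-2.76 ± 0.24) were lower in midbrain, as was Klk6 (-3.54 ± 0.40). Of the neuron-subtype genes, Otx2 (2.82 ± 0.25), Sst (2.79 ± 0.35) and Pvalb (1.40 ± 0.18) were higher in midbrain and Ret (-2.15 ± 0.26), Sox6 (-0.84 ± 0.17) and the neuropeptide Npy (-2.26 ± 0.28) lower. The largest differences were Ndufa4l2 (66.8-fold higher, interval 18.3 to 556), Rpl10 (5.29 ± 1.13, 77.0% of its 3′ end shared), the collagen Col15a1 (5.24 ± 0.52) and angiotensinogen, Agt (4.08 ± 0.35).

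The ependymal and choroid plexus markers had median 1.66, with 11 higher adjusted over the list alone. The tested extracellular matrix genes had median 1.41, with 13 higher over the list alone. The oligodendrocyte and precursor markers had median -1.27, with 7 lower over the list alone. Camera also passed, but not with an estimated correlation (adjusted p = 0.0659 to 0.197), for pan-neuronal markers (1 of 26 lower, 3 over the list alone, median -0.48, adjusted p = 6.63e-05) and synaptic vesicle and release genes (2 of 22 lower, 4 alone, median -0.47, adjusted p = 3.07e-05). This held too for interferon-response genes (1 of 16 lower, 2 alone, median -0.40, adjusted p = 0.00679) and microglia markers (0 of 18 higher and 1 lower, 1 and 4 alone, median -0.63, adjusted p = 0.0101). The same was seen for reactive astrocyte genes (4 of 27 higher, 5 alone, median 0.34, adjusted p = 0.0169) and glycolysis genes (2 of 17 higher, 2 alone, median 0.26, adjusted p = 0.0325). So it was for glutamatergic and cortical neuron genes (0 of 10 lower, 1 alone, median -0.42, adjusted p = 0.0475). With both correlations it passed for fibroblast and pericyte markers (3 of 16 higher, 8 alone, median 0.96, adjusted p = 3.40e-08).

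In edgeR 430 genes differed between the regions at 2 weeks, 294 higher in midbrain and 136 lower. Leaving out cortex 2-week library 1 or 2 gave 71 and 70 calls, and midbrain 2-week library 1 or 2 gave 94 and 86. The edgeR call was then lost for Sox6 and Rpl10 (adjusted p = 0.110 to 0.279) without each of the 4 libraries, and for Sst (adjusted p = 0.0604) without cortex library 1. Losses also followed for Pvalb (adjusted p = 0.0670) without cortex library 2. With the length offset, calls of Pvalb and Rpl10 ended (adjusted p = 0.0525 to 0.327). There were 3209 genes when only these groups were fitted and 2287 in limma with library weights.

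At 4 weeks of shPTB, 18 of 27 tested reactive astrocyte genes (camera adjusted p = 5.32e-24), 11 of 16 tested interferon-response genes (adjusted p = 7.04e-18) and 10 of 19 tested extracellular matrix genes (adjusted p = 2.37e-23) were higher in midbrain than in cortex, and 5 of 11 tested oligodendrocyte and precursor markers (camera adjusted p = 7.70e-11) were lower. Sst stood at 4.67 ± 0.902 CPM in cortex and 77.4 ± 5.12 CPM in midbrain (4.04 ± 0.38), and Reg3g at 0.554 ± 0.512 and 122 ± 9.03 CPM (7.73 ± 0.47). Otx2 (2.99 ± 0.25), Foxa1 (17.8-fold higher, interval 4.66 to 151) and Pvalb (2.06 ± 0.18) were higher in midbrain, and the cortical genes Camk2a (-1.70 ± 0.20) and Fezf2 (-1.41 ± 0.33), with Sox6 (-1.37 ± 0.17) and Npy (-2.25 ± 0.31), were lower. Sprr2b (at least 73.7-fold higher), the carbonic anhydrase Car9 (87.7-fold higher, interval 29.8 to 427) and Elobl (5.99 ± 0.45, 24.0% of its 3′ end shared) were also higher in midbrain, and Aldh1a7 (-3.50 ± 0.39), Mag (-3.24 ± 0.46), Mbp (-3.18 ± 0.22) and the chemokine Pf4 (-3.13 ± 0.44) were lower.

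The reactive astrocyte genes had median 1.43, or 1.29 at bounds, with 21 higher adjusted over the list alone. The interferon-response genes had median 1.76, with 13 higher over the list alone. The extracellular matrix genes had median 2.42, or 2.31 at bounds, with 14 higher over the list alone. The oligodendrocyte and precursor markers had median -2.31, with 7 lower over the list alone. Camera also passed, but not with an estimated correlation (adjusted p = 0.0507 to 0.254), for glutamatergic and cortical neuron genes (4 of 10 lower, 5 over the list alone, median -0.66, adjusted p = 0.00131) and pan-neuronal markers (2 of 26 higher and 5 lower, 2 and 10 alone, median -0.70, adjusted p = 0.0101). Likewise it passed for synaptic vesicle and release genes (3 of 22 lower, 4 alone, median -0.46, or -0.40 at bounds, adjusted p = 0.0402) and neurogenic transcription factors (0 of 11 lower, 2 alone, median -0.86, adjusted p = 0.0290). This held too for cholesterol biosynthesis genes (1 of 22 lower, 3 alone, median -0.32, adjusted p = 0.0173). With both correlations it passed for ependymal and choroid plexus markers (7 of 14 higher, 8 alone, median 2.37, or 2.16 at bounds, adjusted p = 2.28e-13) and fibroblast and pericyte markers (6 of 16 higher and 0 lower, 11 and 1 alone, median 1.88, or 1.40 at bounds, adjusted p = 7.08e-11). It did so too for glycolysis genes (5 of 17 higher, 6 alone, median 0.46, adjusted p = 0.000737).

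In edgeR 1167 genes differed at 4 weeks, 800 higher in midbrain and 367 lower, a higher share of 68.6%, against 86.6% with total-reads scaling, where the median of all genes was 0.25 (at 2 weeks 0.14). Leaving out cortex 4-week library 1 or 2 gave 442 and 464 calls, and midbrain 4-week library 1 or 2 gave 516 and 505. Single calls were then lost for Fezf2 (adjusted p = 0.0700 to 0.212) without each of the 4 libraries, and for Foxa1 (adjusted p = 0.0522 to 0.129) without cortex library 2 and midbrain 1 or 2. With total-reads scaling or the length offset, calls of Foxa1 and Fezf2 ended (adjusted p = 0.0568 to 0.103). The count was 3681 genes when only these groups were fitted and 2877 in limma with library weights.

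Whether the response differed between the regions was tested as the midbrain change minus the cortex change. At 2 weeks this difference was negative for the myelin gene Mbp (-4.53 ± 0.32), the cystine transporter Slc7a11 (-4.30 ± 0.35), the citrate transporter Slc13a5 (-4.19 ± 0.56), Npy (-3.31 ± 0.40) and the signalling ligand Wnt8b (-4.03 ± 0.76). It was positive for Reg3g (7.33 ± 0.51), Ndufa4l2 (5.09 ± 0.67), the methyltransferase Inmt (4.58 ± 0.48) and Cbr2 (4.55 ± 0.56). At 4 weeks it was positive for Reg3g (11.56 ± 0.62), Glycam1 (7.45 ± 0.57), Car9 (7.14 ± 0.62), Sst (4.42 ± 0.91) and Pvalb (1.20 ± 0.25), and negative for Mbp (-4.52 ± 0.32), Slc13a5 (-4.45 ± 0.56), Wnt8b (-4.88 ± 0.73), Npy (-3.30 ± 0.42) and Col22a1 (-3.78 ± 0.36). Sprr2b had 0 reads in midbrain mock and cortex 4-week libraries, so its fitted difference (13.33 ± 2.49) is no bound.

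For the 2-week difference camera passed, but not with an estimated correlation (adjusted p = 0.0574 to 0.298), for pan-neuronal markers (0 of 26 positive and 0 negative, 1 and 5 adjusted over the list alone, median -0.26, adjusted p = 0.00263) and synaptic vesicle and release genes (0 of 22 negative, 4 alone, median -0.52, adjusted p = 6.77e-06). The same was seen for microglia markers (0 of 18, 0 alone, median -0.47, adjusted p = 0.0457). With both correlations it passed for oligodendrocyte and precursor markers (0 of 11 positive and 2 negative, 1 and 4 alone, median -1.19, adjusted p = 3.02e-09) and ependymal and choroid plexus markers (1 of 14 positive, 4 alone, median 1.20, adjusted p = 1.33e-09). For the 4-week difference camera passed, but not with an estimated correlation (adjusted p = 0.0638 to 0.366), for pan-neuronal markers (1 of 26 positive and 0 negative, 2 and 3 over the list alone, median -0.45, adjusted p = 0.0467) and synaptic vesicle and release genes (1 of 22 negative, 4 alone, median -0.43, adjusted p = 0.00435). So it was for glutamatergic and cortical neuron genes (0 of 10 negative, 1 alone, median -0.64, adjusted p = 0.0358) and neurogenic transcription factors (0 of 11 negative, 1 alone, median -0.54, adjusted p = 0.0281). Likewise it passed for glycolysis genes (2 of 17 positive, 2 alone, median 0.35, adjusted p = 0.00515) and extracellular matrix genes (4 of 19 positive and 0 negative, 5 and 1 alone, median 0.41, adjusted p = 0.0129). This held too for fibroblast and pericyte markers (2 of 16 positive and 0 negative, 7 and 1 alone, median 1.29, adjusted p = 0.00323). With both correlations it passed for interferon-response genes (7 of 16 positive, 12 alone, median 1.87, adjusted p = 1.83e-18) and reactive astrocyte genes (10 of 27 positive, 15 alone, median 1.34, adjusted p = 1.12e-19). It did so too for oligodendrocyte and precursor markers (1 of 11 positive and 4 negative, 1 and 7 alone, median -1.91, adjusted p = 2.91e-06) and ependymal and choroid plexus markers (3 of 14 positive, 3 alone, median 2.03, adjusted p = 1.86e-07). It did so too for cholesterol biosynthesis genes (0 of 22 negative, 3 alone, median -0.31, adjusted p = 0.00157).

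In edgeR 100 genes passed at 2 weeks, 62 positive and 38 negative, and 372 at 4 weeks, 278 positive and 94 negative. The positive share at 4 weeks was 74.7%, and 85.6% with total-reads scaling, which put the median of all genes at 0.21. Without both mock libraries numbered 1 or 2 the counts were 1284 and 1559 at 2 weeks and 1773 and 2077 at 4 weeks, and fitting only the groups compared gave 34 and 164. Without cortex mock library 2 the 2-week count was 163, without cortex 2-week library 1 or 2 34 and 26, and without midbrain 2-week library 1 or 2 36 and 33. The 4-week count was 138 and 156 without cortex 4-week library 1 or 2, and 155 and 168 without midbrain 4-week library 1 or 2. At 2 weeks the call was lost for Wnt8b (adjusted p = 0.0681 to 0.272) without cortex mock library 1 or 2, cortex 2-week 1 or 2 and midbrain 2-week 1 or 2, and for Slc13a5 (adjusted p = 0.0520) without midbrain 2-week library 2. At 4 weeks it was lost for Sprr2b (adjusted p = 0.0617 to 1.0) without cortex mock library 1, cortex 4-week 1 or 2 and midbrain 4-week 1 or 2, and for Sst (adjusted p = 0.0725 to 0.634) without cortex mock library 2, cortex 4-week 1 or 2 and midbrain 4-week 1 or 2. A call ended too for Pvalb (adjusted p = 0.0515 to 0.161) without midbrain mock library 2, cortex 4-week 1 or 2 and midbrain 4-week 1 or 2, and for Wnt8b (adjusted p = 0.0639) without cortex 4-week library 1. At 2 weeks, with the length offset, library weights or only the groups compared, calls of Wnt8b and Slc13a5 ended (adjusted p = 0.114 to 0.464). At 4 weeks, with the length offset, library weights, only the groups compared or both mock libraries numbered 1 or 2 left out, calls of Sst, Pvalb, Col22a1, Sprr2b and Wnt8b ended (adjusted p = 0.0614 to 1.0).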

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

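The genes here were reached by the rule for named genes, with no test chosen after seeing the data, and each is listed because the change against mock differed between midbrain and cortex in edgeR (midbrain minus cortex log2 change). At 2 weeks the differences were -3.31 for Npy, 7.33 for Reg3g, 5.09 for Ndufa4l2, 4.58 for Inmt, 4.55 for Cbr2, -4.53 for Mbp, -4.30 for Slc7a11, -4.19 for Slc13a5 and -4.03 for Wnt8b. At 4 weeks they were 4.42 for Sst, -3.30 for Npy, 1.20 for Pvalb, 13.33 for Sprr2b, 11.56 for Reg3g, 7.45 for Glycam1, 7.14 for Car9, -4.88 for Wnt8b, -4.52 for Mbp, -4.45 for Slc13a5 and -3.78 for Col22a1. The Sprr2b value rests on 0 reads in 2 groups and is no bound. Leaving out single libraries ended the calls of Wnt8b and Slc13a5 (adjusted p = 0.0520 to 0.272) at 2 weeks and Sprr2b, Sst, Pvalb and Wnt8b (adjusted p = 0.0515 to 1.0) at 4 weeks.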

How the results depend on the processing

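The alternatives chosen after seeing the data are listed above. For 266 named-gene results, 4114 values over all alternatives kept direction and side of the threshold. Of the others, 258 were no longer past it, 58 newly past it, 39 moved without a call and 5 reversed. Counts of calls stayed within 1.5 times in 115 of the alternative values and did not in 73. The direction of the medians of astrocyte and pan-neuronal markers was kept with the same side of the threshold in 109 values and reversed in 30. Genes under the filter were untested. Shares simulated with 200 changed genes need not hold for 5117 calls (cortex 2-week).

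With RLE size factors, log2 values were -0.011 (pan-neuronal midbrain 2-week). With DESeq2, calls numbered 157 (2-week interaction). Without a count filter, calls numbered 793 (cortex 4 against 2 weeks), 860 (midbrain 4 against 2 weeks), 556 (regions in mock), 826 (regions at 2 weeks), 318 (2-week interaction) and 754 (4-week interaction), and log2 values were -0.013 (pan-neuronal midbrain 2-week) and -2e-04 (astrocyte midbrain 4-week). With the strict filter, log2 values were -0.36 (pan-neuronal cortex 4-week) and -0.12 (pan-neuronal midbrain 2-week). With the length offset, calls numbered 163 (regions in mock), 210 (regions at 2 weeks) and 48 (2-week interaction), and log2 values were 0.17 (astrocyte cortex 2-week) and -0.28 (pan-neuronal midbrain 2-week). Fitting only the groups compared, calls numbered 2608 (cortex 4 against 2 weeks), 3903 (midbrain 4 against 2 weeks), 0 (regions in mock), 3209 (regions at 2 weeks), 3681 (regions at 4 weeks), 34 (2-week interaction) and 164 (4-week interaction), and log2 values were -0.32 (pan-neuronal cortex 4-week) and -0.050 (pan-neuronal midbrain 2-week). Without mitochondrial genes, log2 values were -0.0028 (pan-neuronal midbrain 2-week). Without pseudogenes, log2 values were 0.0018 (astrocyte cortex 4-week). With limma and library weights, calls numbered 1832 (cortex 4 against 2 weeks), 3057 (midbrain 4 against 2 weeks), 88 (regions in mock), 2287 (regions at 2 weeks) and 2877 (regions at 4 weeks), and log2 values were 0.0075 (astrocyte cortex 4-week). Scaled to total reads, calls numbered 9201 (cortex 4-week), 933 (cortex 4 against 2 weeks) and 6833 (midbrain 2-week), and log2 values were -0.14 (Sox9 cortex 2-week), -0.89 (pan-neuronal cortex 4-week), -0.40 (astrocyte midbrain 2-week), -0.66 (pan-neuronal midbrain 2-week), -0.50 (Aqp4 midbrain 2-week) and -0.79 (astrocyte midbrain 4-week). Fry, which tests whether a list moves on balance 1 way, passed for lists with medians -0.12 (astrocyte cortex 2-week, adjusted p = 0.00664), 0.82 (pan-neuronal cortex 2-week, adjusted p = 0.0120), 0.26 (astrocyte midbrain 2-week, adjusted p = 0.00209), 0.069 (astrocyte midbrain 4-week, adjusted p = 0.00874) and -0.60 (pan-neuronal midbrain 4-week, adjusted p = 0.00873). With the replicate block, calls numbered 242 (cortex 4 against 2 weeks), 198 (midbrain 4 against 2 weeks), 126 (regions in mock), 129 (regions at 2 weeks) and 651 (regions at 4 weeks), and with a block across regions in mock 2200 (regions in mock), 316 of them among the 320 called without it. Deviations of same-numbered libraries correlated at 0.715 for the mock pair and between -0.03 and 0.03 for the other pairs, so the numbers were not taken to pair samples across all groups. With 1 library, or both mock libraries of 1 number, left out, calls numbered 2966 to 8385 (cortex 2-week), 3686 to 8590 (cortex 4-week), 242 to 1443 (regions in mock), 26 to 1559 (2-week interaction), 138 to 2077 (4-week interaction), 2424 to 8413 (midbrain 2-week), 3305 to 8884 (midbrain 4-week), 43 to 99 (cortex 4 against 2 weeks), 70 to 94 (regions at 2 weeks), 25 to 52 (midbrain 4 against 2 weeks) and 442 to 516 (regions at 4 weeks). List medians ran -0.16 to 0.11 (astrocyte cortex 2-week), 0.48 to 1.07 (pan-neuronal cortex 2-week), -0.038 to 0.16 (astrocyte cortex 4-week), -0.11 to 0.41 (pan-neuronal cortex 4-week), 0.17 to 0.37 (astrocyte midbrain 2-week), -0.084 to 0.17 (pan-neuronal midbrain 2-week), -0.081 to 0.16 (astrocyte midbrain 4-week) and -1.14 to -0.68 (pan-neuronal midbrain 4-week). Gfap, not called in cortex, ran -0.66 to 0.15 at 2 weeks and -0.64 to 0.17 at 4 weeks, positive without both mock libraries numbered 2. Such fits measure no mock spread and cannot judge calls. The causes of these shifts were not tested, apart from the fewer libraries or genes that some settings keep.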

Other observations

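The tests of near-identical copies, batch, mislabelling, scaling and depth were chosen after the results were seen, and those of mitochondrial ribosomal RNA and nuclear respiratory genes before. The 13 mitochondrial messenger RNAs had medians of 1.68, 2.36, 2.00 and 2.12 against mock (cortex 2 and 4 weeks, midbrain 2 and 4 weeks), and 12, 13, 13 and 13 of 13 rose in edgeR. The complex I subunit genes mt-Nd4l and mt-Nd6 had log2 changes of 4.37 to 5.27 and 3.02 to 4.27. The 2 mitochondrial ribosomal RNAs had medians of 0.11, 0.40, 0.13 and 0.16. Of 83 tested nuclear genes of respiratory chain and ATP synthase subunits, 21, 24, 27 and 29 rose and 5, 6, 2 and 4 fell, with medians of 0.22, 0.08, 0.26 and 0.30. With libraries scaled to total reads, the medians stayed positive for the messenger RNAs (1.04, 1.37, 1.34 and 1.28) and turned negative for the ribosomal RNAs (-0.69, -0.75, -0.57 and -0.75) and the nuclear genes (-0.55, -1.02, -0.41 and -0.60).

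Mitochondrially encoded genes took 36.4 to 48.3% of reads in the 8 shPTB libraries and 16.9 to 22.7% in the 4 mock libraries. Priming on mitochondrial ribosomal RNA alone is argued against, since the lowest of the 4 medians of the messenger RNAs was 1.68. A larger mitochondrial content could also raise the nuclear-encoded subunits, whose highest median was 0.30, between the 0.2 and 0.5 set before the test, so it stays open. RNA quality is not given in the sources used here, and the hairpin, the medium and time in culture, not separable against mock, remain untested. At 4 against 2 weeks the messenger RNAs had median 0.68 in cortex, where 1 of 13 rose in edgeR, and 0.25 in midbrain (-0.44 to 0.65).

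The pan-neuronal markers did not pass camera against the other genes in any of the 4 comparisons with mock (adjusted p = 0.182, 0.843, 1.0 and 0.159), while fry passed upwards in cortex at 2 weeks and downwards in midbrain at 4 weeks. Tubb3 and Dcx fell in all 4. Mislabelled shPTB libraries are argued against, since 8 of 8 lay lower than both mock libraries of their region for Ptbp1 and higher for Ptbp2. Too little depth stays open, since the 26 markers, of which at least 46.2% passed in each comparison, were kept by read count. Scaling stays open, since the shifts of the list and of all genes differed by at most 0.0355 with RLE, total reads and leaving out mitochondrial genes (list shifts of -0.0041 to -0.0056), as do the hairpin and the medium, not tested apart.

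Chosen after their values were seen, 2 genes had 10 CPM or more in every library of mock or of shPTB and 0 reads in every library of the other: the unprocessed pseudogene Gm10222 (chromosome 1, 24612407 to 24612700), at 643 to 1211 CPM in mock, and the processed pseudogene Gm12218 (chromosome 11, 53902757 to 53903155), at 22.6 to 32.4 CPM with shPTB. Reads shared between near-identical gene copies could explain them, since 50% of the 2 genes, against 4.64% of other tested genes, have most of their 3′ end in another gene (Fisher's exact test, two-sided p = 0.0907), which 2 genes cannot decide. A batch cannot be told apart from the groups, as mock and shPTB libraries share none that is known. Deviations of same-numbered mock libraries correlated at 0.715 across genes, and the split of mock libraries by number also gave 2 genes of this kind. No biological explanation was tested for them.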
